A study of Mus musculus with 6 samples.

How the data were processed

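Poly-A RNA was selected with oligo-T beads from 3 µg of RNA per sample, and libraries were made with the NEBNext Ultra kit, per the labels' protocols. The deposited table gives read counts and FPKM values for 54532 genes in each of the 6 samples, with 0 per-sample columns left unmatched and no row that names no gene. Counts per gene were made by the authors with featureCounts version 1.5.0-p3, per the series design text, and the genome build is mm10, per the submitters' processing notes. The aligner, the gene annotation and the strand setting are not given in the sources used here. FPKM values were computed by the authors from the counts and the gene lengths, per the series design text. For abundant genes, the ratio of counts to FPKM is, relative to the first DMSO library, 0.950 and 0.993 in the other DMSO libraries and 0.888, 0.956 and 0.924 in the baicalin libraries, whereas the count totals stand at 0.945, 0.988, 0.994, 1.03 and 1.01. The FPKM columns were therefore not scaled by the column totals, and lie close to the TMM scaling used here (0.947, 0.989, 0.900, 0.959 and 0.930). The counts carried the main test, and the FPKM values an alternative.

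Samples were grouped by the treatment label, 3 DMSO and 3 baicalin, and the design has 1 contrast. Gene names and coordinates were taken from GENCODE M21, which is on the same mouse assembly as mm10. Of the gene identifiers 54495 are in that annotation and 37 are not. For 27 names that a spreadsheet had turned into dates the annotation's symbol was used, and where a name occurs in more than 1 row (207 rows) the row with the most reads stood for it in a gene list. No read was counted for 27286 genes.

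Counts were tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM normalization, robust quasi-likelihood fits and treatment as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called, and a log2 fold change of at least 1 marks 2-fold. CPM values are scaled by TMM factors (from 0.945 to 0.967 in baicalin and from 1.04 to 1.05 in DMSO), and every adjusted p of a single gene comes from this test unless another is named. The biological coefficient of variation was 4.61%, so that log2 fold changes as small as 0.08 were called. Gene lists, 35 in number, were fixed before the data were examined, and the 33 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Beside these, camera with an estimated correlation and fry were run. Member counts adjusted over the list alone equal those over all genes except where both are given.

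The rule for genes named in the text, fixed at the same time as the lists, takes 16 fixed genes, the 10 largest rises and 10 largest falls among called genes with a symbol (predicted genes, clones and pseudogenes left out), a mean of at least 5 CPM and no overlap between the groups, up to 5 genes of each list among its called members with a mean of at least 5 CPM, and the 5 genes with the smallest p in each direction. Genes outside the rule are said to be named after their values were seen, except those given only because their exons or sequence overlap a named gene. The rule gives 165 genes, of which the text names fewer, and some genes are not reported here. Exons of 32 of them overlap those of another gene with reads, and for 8 the other gene has over 50% as many reads. Because the strand setting is not known, such genes are uncertain, as are genes with near-identical copies. The lower bound of a fold against a group without reads takes 3 counts over the group as its floor.

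The test was checked on simulated counts drawn from the means and library sizes of the 13479 genes that passed the filter there. Of the changed genes it called 38.8% at 1.2-fold, 78.0% at 1.5-fold, 93.5% at 2-fold and all 49 at 4-fold, with 20 false calls among 13263 unchanged genes. A list shifted by 1.5-fold was recovered, and 2 of the 32 other lists were called beside it. Most genes were left unchanged there, and genes were drawn independently of each other. The check therefore cannot test the scaling where most genes change, nor the preset correlation between genes.

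The alternatives fixed in advance were DESeq2 1.42.0, limma-voom, RLE factors, library size alone, no low-count filter, a stricter filter of at least 1 CPM in all 3 libraries of a group, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 3 libraries, the same without a filter, and leaving out each library in turn. A fit with lowess trends on exon length and transcript GC removed from each library (span 0.3) was added after seeing the data. Bootstrap intervals cover 95% from 10000 draws over list members, which are treated as independent, so they do not measure the spread between samples. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.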

Results

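RNA was sequenced from 6 samples of 3T3 cells, a mouse fibroblast line, which the labels describe as wild-type adipocytes. The subline and the way the cells were made into adipocytes are not given in the sources used here, and transcripts of the fat cell markers Lep and Slc2a4 were near 0 in every library. Of these, 3 received DMSO, the solvent, and 3 received 200 µM baicalin, a flavone glucuronide found in Scutellaria roots. The duration of treatment is not given in the sources used here, and nothing in them says whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Total counts were 17711950, 16730594 and 17490650 in the DMSO libraries and 17598666, 18326874 and 17924970 in the baicalin libraries. Each total allows a gene without reads a level of at most 0.179 CPM, which covers counting error only. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 2.83 and 4.35 for the 6 within-group pairs, so no pair was counted as 1 library. This does not show that they came from separate cultures. At least 1 read was found for 21232 ± 187 genes in DMSO and 19493 ± 397 genes in baicalin (SD, n = 3 each).

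The single contrast of the series asks how baicalin changes the transcriptome of these cells. The series title ties the treatment to lipid accumulation, metabolic reprogramming and the adenosine A1 receptor. The responses included a rise of the xenobiotic-metabolising enzyme Cyp1a1 and rises of glycolytic, antioxidant, stress-response and inflammatory genes. They also included falls of interferon-stimulated genes and of several markers of mature fat cells. The list calls of these falls were lost with an estimated correlation (adjusted p = 0.075 for the interferon-stimulated genes and adjusted p = 0.383 for the fat cell markers). Of 13728 genes tested, 4618 were higher and 4676 lower in baicalin, and 4434 were not called, with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. A change of at least 2-fold was reached by 2053 genes, of which 720 were higher and 1333 lower. On the log2(FPKM + 1) scale 734 genes passed 2-fold, 744 without a filter, and 1185 on the log2(FPKM + 0.1) scale. The 2 groups did not overlap for 70.2% of the tested genes, where chance gives 10%. Scaling by library size alone, with no correction for composition, shifted the median log2 fold change of all genes by -0.13 and gave 3472 higher and 5811 lower genes, so that 37.4% of the called genes were higher instead of 49.7%. All fold changes that follow are relative to the TMM scaling.

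Among the 10 largest rises, Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), the classical target of the aryl hydrocarbon receptor, had no read in any DMSO library and 1110, 1249 and 1139 reads in the baicalin libraries. It was at least 1227-fold higher in baicalin, taking 3 counts over the DMSO group as the floor. The carboxylesterase Ces1g (ENSMUSG00000057074, chromosome 8, 93302369 to 93337308) rose from 1.10 ± 0.31 to 43.1 ± 2.75 CPM (SD, n = 3 each), a 38.7-fold change. Il33, a cytokine of the interleukin-1 family, rose 34.5-fold, the bradykinin receptor Bdkrb2 31.6-fold, Cyfip2 26.6-fold, Nos2, the inducible nitric oxide synthase, 24.3-fold, Csf3, which encodes granulocyte colony-stimulating factor, 23.9-fold, A4galt 22.7-fold and Aldh3a1 18.6-fold. Bst1 rose 20.9-fold, but its exons overlap those of the opposite-strand gene Fbxl5 over 98 bp, and Fbxl5 had more reads. By the same rule of at least 5 CPM on average and no overlap between the groups, the largest falls included those of Apod, which encodes a lipid-binding apolipoprotein, from 713 ± 57.3 to 65.2 ± 5.09 CPM (10.9-fold lower), Ear2 (10.4-fold), Capns2 (9.33-fold), the non-coding RNA Dnm3os (8.72-fold), Sema3a (7.71-fold), Sult1a1 (7.21-fold), whose exons overlap those of the opposite-strand gene Sgf29 over 61 bp, and Ogn, a proteoglycan of the extracellular matrix (ENSMUSG00000021390, chromosome 13, 49608046 to 49624501, 7.19-fold, adjusted p = 3.11e-48). By the smallest p, the leading rises also held the BMP antagonist Grem1 (10.9-fold, adjusted p = 9.83e-51), the acute-phase gene Saa3 (9.19-fold), Wisp2 (16.9-fold), Nqo1 (12.9-fold) and Slpi (18.5-fold). The leading falls held Maf (4.50-fold), the smooth-muscle actin gene Acta2 (5.86-fold), Slc5a3 (3.39-fold) and the growth hormone receptor Ghr (3.32-fold). Exons of Slc5a3 overlap those of Mrps6 on the same strand over 159 bp.

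**Figure D1:**
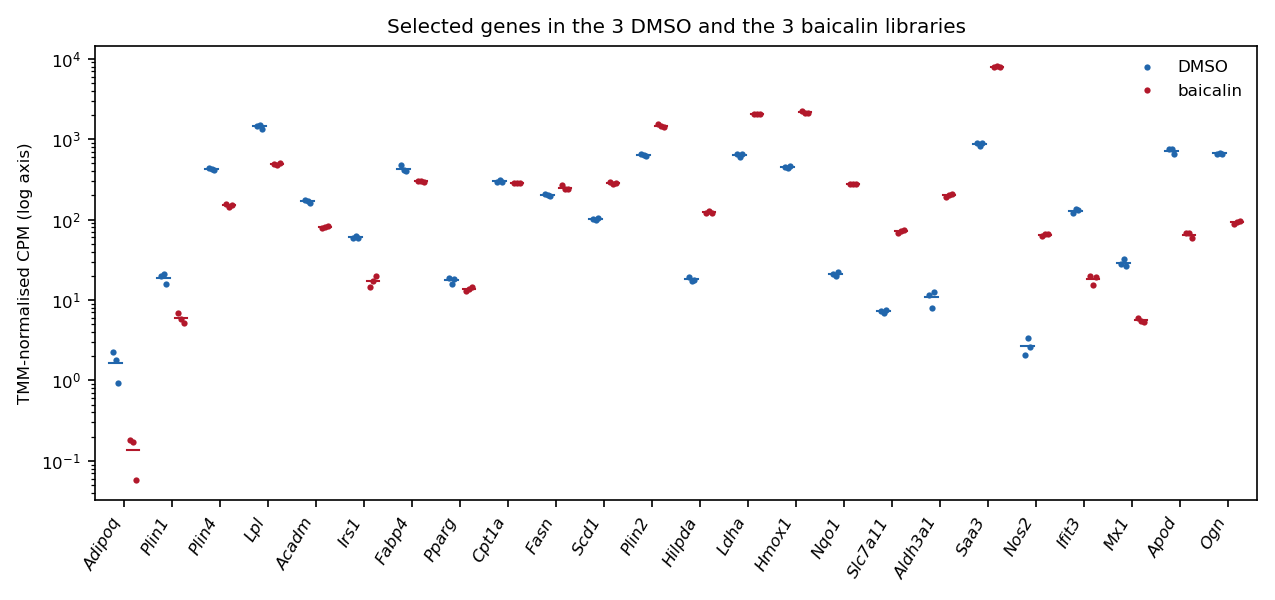
TMM-normalised CPM, on a log axis, of 24 named genes in each of the 3 DMSO (blue) and 3 baicalin (red) libraries, with the group mean as a short line. Cpt1a lay at 298 and 287 CPM in the 2 groups, while Nqo1, Slc7a11, Aldh3a1 and Nos2 were higher, and Plin1, Lpl, Apod and Ogn lower, in each of the 3 baicalin libraries.

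Genes of detoxification and of the antioxidant response rose together. Of 32 tested targets of NRF2, the transcription factor of the oxidative stress response, 31 were higher and 1, the catalase gene Cat, was lower (log2 fold change -1.16), with a median of 1.18 (camera adjusted p = 4.42e-32, and adjusted p = 0.0203 with an estimated correlation). The quinone reductase Nqo1 rose from 21.3 ± 1.2 to 275 ± 2.03 CPM (SD, n = 3 each, log2 fold change 3.69, SE 0.05), the cystine transporter Slc7a11 rose 9.81-fold and the heme oxygenase Hmox1 4.80-fold. Among 8 tested targets of the aryl hydrocarbon receptor 6 were higher and 2 lower, with a median of 1.65 (adjusted p = 8.46e-18, and adjusted p = 0.0203 with an estimated correlation). Cyp1a1 is the highest of these, so setting it to its lower bound cannot move the median, and the p-values were not recomputed at that bound. Nqo1 stands in both this list and the NRF2 list. The 2 that fell, Fam107a (log2 fold change -3.83) and Ugt1a6a (-0.97), are named after their values were seen. In the pentose phosphate pathway and NADPH list 8 of 10 genes were higher and 2, Idh1 and Rpia, lower, with a median of 0.67 (adjusted p = 4.87e-06). That call was lost with an estimated correlation (adjusted p = 0.0837). The rises included Pgd and Taldo1, each 2.43-fold, and G6pdx at 2.48-fold, whose exons overlap those of the opposite-strand gene Ikbkg over 418 bp. Of the 10 members, 5 also stand in the NRF2 list. The fall of Rpia was small (-0.28), and its call was lost without DMSO replicate 1 (adjusted p = 0.0608) or baicalin replicate 1 (adjusted p = 0.078).

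Stress-response genes rose as well. For 33 tested targets of ATF4 and CHOP, the transcription factors of the integrated stress response, 32 were higher and none lower, with a median log2 fold change of 1.09 (adjusted p = 2.42e-32, and adjusted p = 0.0179 with an estimated correlation). Trib3, a pseudokinase induced by CHOP, rose from 19.2 ± 1.36 to 86.2 ± 4.22 CPM, and Chac1, which degrades glutathione, from 16.1 ± 1.42 to 58.2 ± 4.50 CPM (SD, n = 3 each). All 23 tested chaperones of the endoplasmic reticulum were higher, with a median of 0.94 (adjusted p = 1.06e-20, and adjusted p = 0.0203 with an estimated correlation), among them Sdf2l1 (3.06-fold) and Hyou1 (2.67-fold). Of 19 heat shock proteins 15 were higher and none lower, led by Hspa4l at 4.01-fold, Hsph1 at 2.23-fold and the co-chaperone Stip1 at 2.22-fold. Their list had a median of 0.55 (adjusted p = 4.87e-06), a call lost with an estimated correlation (adjusted p = 0.0798).

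Transcripts of most glycolytic genes were higher. Of 23 tested genes of glycolysis and lactate export 20 were higher and 1 lower, with a median log2 fold change of 1.16 (adjusted p = 7.08e-25, and adjusted p = 0.0262 with an estimated correlation). The lactate dehydrogenase gene Ldha rose from 634 ± 26.1 to 2052 ± 16.7 CPM (SD, n = 3 each, 3.24-fold) and the pyruvate kinase gene Pkm from 1204 ± 36.4 to 3508 ± 88.8 CPM (2.91-fold). The 1 fall was that of Ldhb (-0.15, adjusted p = 0.046), a call lost without DMSO replicate 1 (adjusted p = 0.232), DMSO replicate 3 (0.137), baicalin replicate 1 (0.341) or baicalin replicate 3 (0.0638), and with DESeq2 (0.219). Gapdh is reported as uncertain, because the genome holds many near-identical copies of it. It had 189, 201 and 195 reads in DMSO against 3919, 323 and 4570 reads in baicalin (adjusted p = 0.044), and its call was lost on leaving out any of the libraries except baicalin replicate 2 (adjusted p from 0.11 to 0.129) and with limma-voom (adjusted p = 0.289). Targets of the hypoxia-inducible factors, 6 of which are also in the glycolysis list, were higher for 20 of 23 genes and lower for 2, with a median of 1.19 (adjusted p = 7.64e-19, and adjusted p = 0.0429 with an estimated correlation). The oxidoreductase Ero1l rose 5.41-fold and Egln1, an oxygen sensor, 3.15-fold. The 2 falls, of Kdm3a (-0.20) and Ndrg1 (-0.17), were small. After removal of the length and GC trends Kdm3a stood at 0.03, and Ndrg1 at -0.16, close to its value before, although no longer called (adjusted p = 0.0656). The call of Ndrg1 was also lost without DMSO replicate 2 (0.0903), DMSO replicate 3 (0.19), baicalin replicate 1 (0.131) or baicalin replicate 3 (0.216).

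Of 75 nuclear genes of oxidative phosphorylation 51 were higher and 3 lower (53 and 3 adjusted over the list alone), with a median log2 fold change of 0.23 (adjusted p = 0.00122). That list's call was lost with an estimated correlation (adjusted p = 0.364) and after removal of the length and GC trends (median 0.09, adjusted p = 0.289). Cycs, which encodes cytochrome c, rose 1.93-fold and Uqcrq 1.76-fold, whereas Cox7b was 1.30-fold lower, Ndufa6 1.16-fold lower and Atp5j2, named after its value was seen, lower by a log2 fold change of -0.12. Of 12 mitochondrially encoded subunits 6 were lower and none higher, with a median of -0.29 and no call (adjusted p = 0.27). With the length and GC trends removed the median was -0.07 (adjusted p = 0.497), and without DMSO replicate 3 the list was called lower (adjusted p = 0.00902). The cytochrome b gene mt-Cytb was lower (log2 fold change -0.52), a call lost without baicalin replicate 1 (adjusted p = 0.0568). The share of counts from mitochondrial genes was 1.73% ± 0.14 in DMSO and 1.33% ± 0.06 in baicalin (SD, n = 3 each). The list of the tricarboxylic acid cycle and pyruvate entry had 15 of 27 genes higher and 3 lower, with a median of 0.20 (0.10 with the length and GC trends removed), and was not called (adjusted p = 0.182). In it Ogdh (1.63-fold) and Mdh2 (1.59-fold) rose, and Idh2 (1.72-fold), Idh1 (1.18-fold) and Sucla2, named after its value was seen, fell. Fatty acid oxidation was not called either (adjusted p = 0.789). It had 12 of 28 genes higher and 9 lower, a median of 0.01, a mean of -0.04 and a test that pointed down. Cpt1a, the gate of fatty acid entry into mitochondria (ENSMUSG00000024900, chromosome 19, 3322334 to 3385733), was at 298 ± 7.37 CPM in DMSO and 287 ± 1.54 CPM in baicalin, a difference that was not called (log2 fold change -0.05, SE 0.04, adjusted p = 0.226). With library-size scaling alone it was called lower, at -0.18. Acadm, the medium-chain acyl-CoA dehydrogenase gene, was 2.08-fold lower, and Ppargc1a, a coactivator of mitochondrial biogenesis, 2.85-fold lower, while Acot2 was 1.60-fold higher. Genes of branched-chain amino acid catabolism were split as 5 higher and 9 lower of 21 (median -0.02, adjusted p = 0.544), with Acadsb 1.61-fold lower and Bcat2 1.38-fold higher.

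Markers of mature fat cells fell in part. Of 25 markers in the list 16 had enough reads to test. Of these 11 were lower and 4 higher (11 and 5 adjusted over the list alone), with a median log2 fold change of -0.70 (adjusted p = 0.00929). That call was lost with an estimated correlation (adjusted p = 0.383). Adipoq, which encodes the adipokine adiponectin (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028), had 42, 31 and 17 reads in DMSO and 3, 3 and 1 in baicalin (log2 fold change -3.54, SE 0.51, adjusted p = 2.24e-08). Plin1, which coats the lipid droplets of fat cells, fell from 18.9 ± 2.79 to 5.93 ± 0.84 CPM, the lipoprotein lipase gene Lpl from 1443 ± 79.6 to 491 ± 8.06 CPM, and the fatty acid binding protein gene Fabp4 from 429.7 ± 37.9 to 298 ± 6.08 CPM (SD, n = 3 each). Plin4 was 2.84-fold lower and Pparg, the master regulator of fat cell formation, 1.28-fold lower. The 4 that rose were the lipase genes Lipe (1.51-fold) and Pnpla2 (1.41-fold), which release fatty acids from stored fat, the transcription factor gene Cebpb (2.08-fold) and Agt (log2 fold change 0.29), the last named after its value was seen. Cebpa was at 0.98 ± 0.14 CPM in DMSO and 1.57 ± 0.21 CPM in baicalin and was not called (adjusted p = 0.0579). It was called with the stricter count filter (adjusted p = 0.0499). The markers Lep, with 2 reads in all 6 libraries together, and Slc2a4, with 5 reads in DMSO and 1 in baicalin, were too low to test. Ucp1, the uncoupling protein of brown fat, had 1 read in all.

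All 17 tested genes of de novo fatty acid synthesis were higher, with a median log2 fold change of 0.56 (adjusted p = 7.8e-07, lost with an estimated correlation, adjusted p = 0.0798). The desaturase Scd1 rose from 101 ± 2.88 to 285 ± 10.2 CPM and Fasn, the fatty acid synthase, from 202 ± 6.39 to 248 ± 15.6 CPM (SD, n = 3 each). Scd2 was 2.58-fold higher. For cholesterol synthesis and uptake 18 of 24 genes were higher and 2, Hmgcs1 and Insig1, lower, with a median of 0.47 (adjusted p = 0.00511, lost with an estimated correlation, adjusted p = 0.0798). Mvd, an enzyme of the mevalonate pathway, rose by a log2 fold change of 1.17. Triglyceride synthesis had 8 of 14 genes higher and 4 lower (median 0.25, adjusted p = 0.308). Dgat2, which catalyses its last step, was 2.92-fold higher, Lpin1 1.83-fold lower and Agpat2 1.54-fold lower. The other two genes that fell, Gpd1 and Agpat3, are named after their values were seen. In the list of lipolysis and lipid droplet proteins 7 of 16 were higher and 5 lower (7 and 6 adjusted over the list alone), with a median of 0.05, a mean of -0.13, a test that pointed up and no call (adjusted p = 0.182). Hilpda, an inhibitor of lipolysis, rose 6.81-fold and the ubiquitous droplet protein Plin2 2.31-fold, while Plin1 and Plin4 fell as given above, with Cidec, Ces1d and Bscl2, named after their values were seen. Insulin signalling genes were split as 4 higher and 15 lower of 24 (median -0.22, adjusted p = 0.182), and with the length and GC trends removed the median was 0.01. The insulin receptor substrate Irs1 fell 3.51-fold and Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, had a log2 fold change of -0.58, while Socs3 rose 3.79-fold and Irs2 1.69-fold. Ptpn1 and Pik3cb, named after their values were seen, were the other two that rose. Of 25 markers of brown or beige fat cells 8 were tested, with 3 higher and 2 lower (2 and 2 adjusted over the list alone, median 0.03, adjusted p = 0.968). They were Fgf21, Tnfrsf9 and Slc6a8 on one side and Ppargc1a and Ppargc1b on the other, of which Fgf21, Tnfrsf9 and Ppargc1b are named after their values were seen. Slc6a8 (log2 fold change 0.09, adjusted p = 0.049) was at -0.04 with library-size scaling alone and was not called without DMSO replicate 1 (adjusted p = 0.14), DMSO replicate 3 (0.0715) or baicalin replicate 3 (0.181).

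The adenosine A1 receptor gene Adora1 (ENSMUSG00000042429, chromosome 1, 134199223 to 134235431), which the series title names, had 1 read in the 6 libraries together, in a DMSO library, so that its response was not detectable at this depth. Its exons overlap those of Mybph, on the opposite strand, over 1162 bp. Adora2a had 7 reads in DMSO and 6 in baicalin, and Adora3, named after its value was seen, had none. Adora2b was measured at 2.43 ± 0.48 CPM in DMSO and 2.63 ± 0.38 CPM in baicalin (SD, n = 3 each) and was not called (log2 fold change 0.11, SE 0.24, adjusted p = 0.697). Among 13 tested genes of adenosine receptors and adenosine metabolism 5 were higher and 4 lower, with a median of 0.11 (adjusted p = 0.503). Ampd3, an AMP deaminase, rose 3.13-fold, Ahcy, which hydrolyses S-adenosylhomocysteine to adenosine, 2.03-fold and Ampd2 1.43-fold. The purine nucleoside phosphorylase gene Pnp was 1.95-fold lower and the nucleoside transporter gene Slc29a3 1.65-fold lower. The remaining called members, Ada and Slc29a2 among the rises and Adk and Slc29a1 among the falls, are named after their values were seen.

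Inflammatory genes rose while interferon-stimulated genes fell. Of 34 cytokines and NF-kB targets 28 had enough reads to test. Of these 22 were higher and 4 lower, with a median log2 fold change of 0.92 (adjusted p = 4.03e-20, and adjusted p = 0.0179 with an estimated correlation). Members too low to test were Tnf (2 reads in DMSO and 0 in baicalin), Il1b (5 and 1), Icam1 (1 and 1), Ccl20 (16 and 2), Csf2 (29 and 23) and Cxcl2 (0 and 12). They are named after their values were seen. The macrophage marker list was also called higher (adjusted p = 0.0453, lost with an estimated correlation, adjusted p = 0.198), with Cd14 4.70-fold higher. Saa3 rose from 869.7 ± 33.7 to 7989 ± 94.1 CPM, Nos2 from 2.67 ± 0.66 to 64.8 ± 2.32 CPM and Csf3 from 0.48 ± 0.20 to 11.6 ± 0.30 CPM (SD, n = 3 each). The falls were those of the chemokines Ccl9 (2.36-fold) and Cxcl12 (1.44-fold) and of C3 and Csf1, the last pair named after their values were seen. Of 30 tested interferon-stimulated genes 26 were lower and 3 higher, with a median of -0.91 (adjusted p = 4.41e-13). That call was lost with an estimated correlation (adjusted p = 0.075). Mx1, an antiviral GTPase, fell from 29.0 ± 2.82 to 5.56 ± 0.29 CPM (SD, n = 3 each). Ifit3 and Ifit3b, which are close paralogs and can share reads, fell 7.17-fold and 7.06-fold. Psmb8 and Psmb9, subunits of the immunoproteasome, were 1.79-fold and 1.44-fold higher, and Ifi27, named after its value was seen, also rose. Exons of Psmb9 overlap those of the opposite-strand gene Tap1 over 212 bp, and Tap1 had more reads. Immediate early genes had 15 of 25 members higher and 2, Klf6 and Nr4a2, lower, with a median of 0.49 (adjusted p = 3.19e-09, lost with an estimated correlation, adjusted p = 0.0679). Ier3 was 8.72-fold higher and Maff 5.25-fold higher. Fosl1 was 7.58-fold higher, with exons that overlap those of the opposite-strand gene Ccdc85b over 1163 bp. The call of Nr4a2 (-0.40) was lost without DMSO replicate 2 (adjusted p = 0.125), DMSO replicate 3 (0.0608), baicalin replicate 1 (0.0695) or baicalin replicate 3 (0.176).

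**Figure D2:**
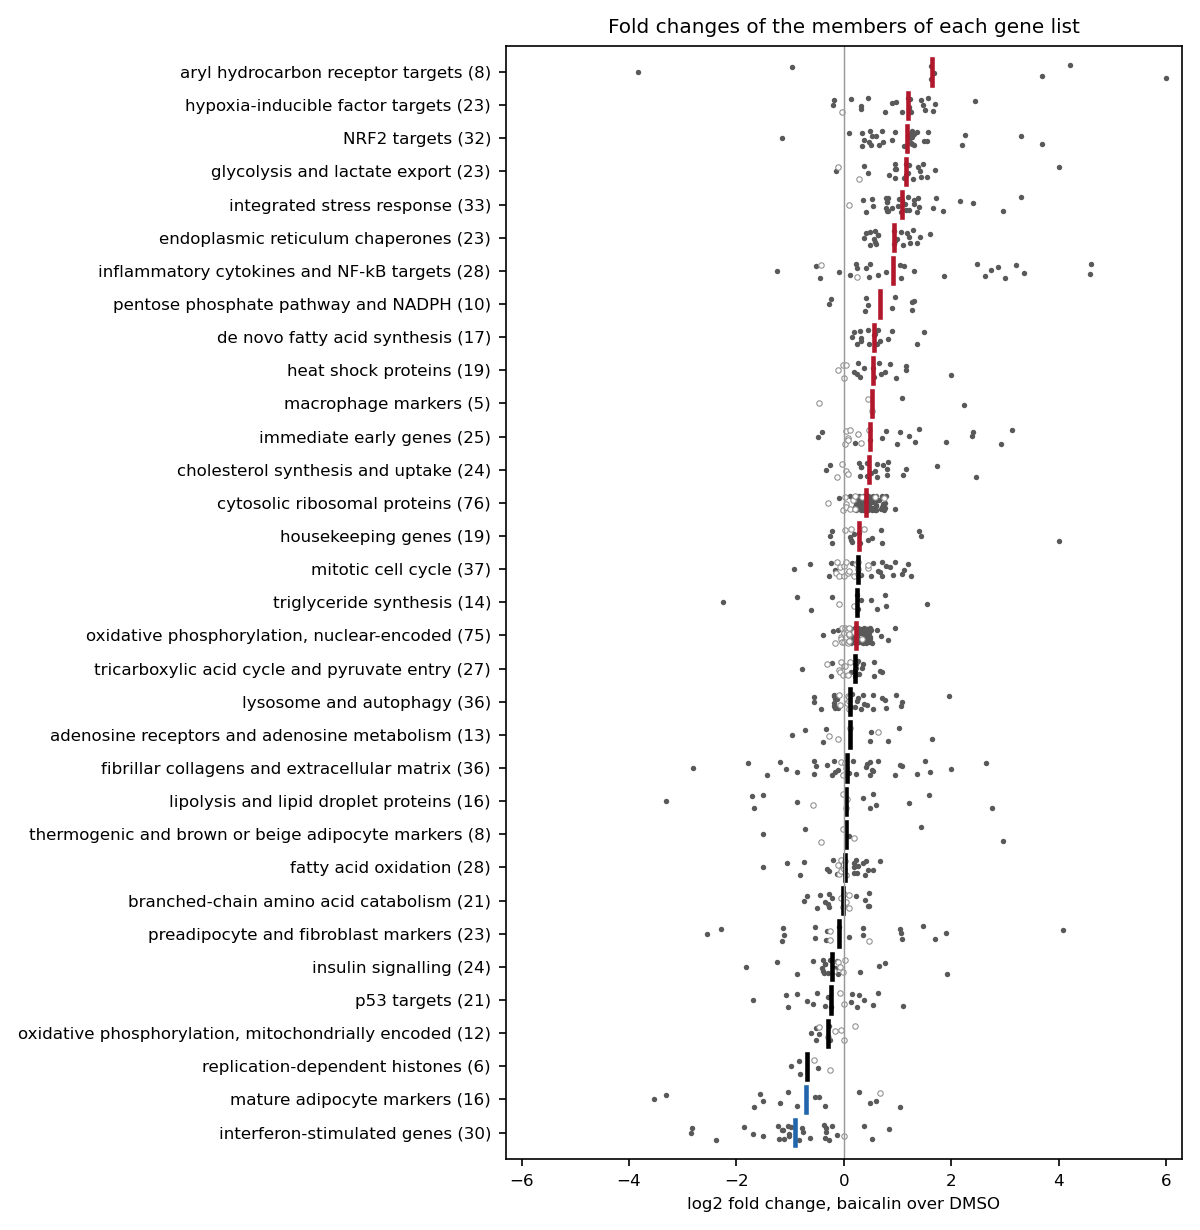
Log2 fold change (baicalin over DMSO) of each tested member of the 33 gene lists with at least 5 tested members, ordered by the list's median, with the number of tested members in brackets. Filled points are genes with an adjusted p under 0.05, open points the rest. Vertical bars mark medians, in red for 16 lists called higher, in blue for 2 called lower and in black for the others. Cyp1a1, which had no read in DMSO, lies beyond the axis and is drawn at its right edge.

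Genes of the matrix and of fibroblasts went both ways. For fibrillar collagens and the extracellular matrix 18 of 36 genes were higher and 14 lower (median 0.07, adjusted p = 0.182). Mmp3, a matrix metalloprotease, rose 6.30-fold and Timp1, an inhibitor of such proteases, 3.05-fold, while Col8a1 fell 3.46-fold and the lysyl oxidase gene Lox 2.27-fold. Preadipocyte and fibroblast markers were split as 10 higher and 10 lower of 23, with a median of -0.08, a mean of 0.14, a test that pointed down and no call (adjusted p = 0.789). Among them Wisp2 rose 16.9-fold, Ly6a 3.75-fold and Thy1 2.13-fold, while Acta2 fell 5.86-fold and Postn 4.89-fold. Mitotic cell cycle genes had 16 of 37 members higher and 5 lower (median 0.27, adjusted p = 0.213), with Ccnb1 2.4-fold and Aurka 2.28-fold higher and Tpx2 1.90-fold and Rrm1 1.55-fold lower. The other falls in this list were those of E2f1, Mki67 and Pcna, named after their values were seen. Of 21 p53 targets 8 were higher and 11 lower (median -0.23, adjusted p = 0.118). With the length and GC trends removed this list was called lower (adjusted p = 0.0462). Trp53inp1 was 3.22-fold lower and Plk2 2.15-fold higher. Lysosome and autophagy genes had 18 of 36 members higher and 11 lower (median 0.12, adjusted p = 0.0748). The list was called higher without baicalin replicate 2 (adjusted p = 0.0386) or baicalin replicate 3 (adjusted p = 0.0478). Gpnmb rose 3.91-fold and the cathepsin gene Ctsl 2.11-fold, and Mcoln1 fell 1.47-fold.

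Cytosolic ribosomal protein genes were higher for 63 of 76 and lower for 1, Rps3a1, with a median of 0.41 (adjusted p = 4.57e-11), which was 0.26 with the length and GC trends removed. That call was lost with an estimated correlation (adjusted p = 0.257). Rpsa was 1.72-fold and Rplp1 1.70-fold higher, and both belong to a family with many processed copies in the genome, with which reads can be shared. The call of Rps3a1 (-0.08) was lost on leaving out any library except DMSO replicate 2 (adjusted p from 0.0513 to 0.271). Among 19 genes often taken as housekeeping controls 13 were higher and 3 lower, with a median of 0.29 (adjusted p = 0.00289, lost with an estimated correlation, adjusted p = 0.257). The rises included Gapdh, reported as uncertain above, the glycolytic enzyme gene Pgk1 (2.70-fold) and the transferrin receptor gene Tfrc (2.65-fold). The falls were those of Actb (1.17-fold), Tuba1a (1.19-fold) and Tbp, the last named after its value was seen. Without baicalin replicate 2, where Gapdh had 323 reads, the camera adjusted p was 9.85e-07. Of the members, 2 also stand in the glycolysis list, 2 in the ribosomal protein list and 1 in the nuclear oxidative phosphorylation list. With library-size scaling alone the medians of the extracellular matrix (-0.06), lipolysis (-0.08), fatty acid oxidation (-0.11), adenosine (-0.02), brown fat (-0.09) and lysosome (-0.01) lists turned negative. None of these 6 lists was called by camera at the preset correlation. The same scaling moved the medians of preadipocyte markers to -0.21, triglyceride synthesis to 0.12, the tricarboxylic acid cycle to 0.07, nuclear oxidative phosphorylation to 0.11, the mitotic cell cycle to 0.14, p53 targets to -0.36, branched-chain amino acid catabolism to -0.14, insulin signalling to -0.35 and housekeeping genes to 0.16.

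Markers of other cell types were mostly too low to test. Of 15 macrophage markers 5 were tested, and 2 of them were higher, Cd14 (4.70-fold) and Cd68, the last named after its value was seen (list median 0.52, adjusted p = 0.0453, lost with an estimated correlation, adjusted p = 0.198). The list was not called without baicalin replicate 1 (adjusted p = 0.126) or baicalin replicate 3 (adjusted p = 0.057), nor with the length and GC trends removed (adjusted p = 0.105). Of 12 endothelial markers 2 were tested, and Vwf, named after its value was seen, was higher (log2 fold change 2.01). In the myogenic list 4 of 15 genes were tested, of which Des (2.13-fold), Mylpf and Tnnt3 were higher and Ttn lower, the last 3 named after their values were seen. Replication-dependent histone genes, whose transcripts lack a poly-A tail, had 6 tested members, of which 4 were lower and none higher (5 lower adjusted over the list alone, median -0.68, adjusted p = 0.38). Hist1h2bc was 1.39-fold lower, and Hist1h1e, Hist1h2ac and Hist2h4, named after their values were seen, were the others.

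Fold changes were related to the length and base composition of the genes. Across the 13714 tested genes with both values, which are not independent replicates, Spearman's rho of the log2 fold change was -0.19 with exon length and 0.31 with transcript GC. With the genes sorted into 5 bins of equal size, 15.3% were called higher and 55.1% lower in the bin of lowest GC, and in the bin of highest GC 47.4% were higher and 20.5% lower. With both trends removed, an alternative chosen after seeing the data, 4567 genes were higher and 4302 lower. Of the 7519 genes called in both fits, 262 had opposite directions, and 1768 of the genes called with TMM scaling were no longer called. The list medians then stood at 0.22 for the extracellular matrix, 0.07 for brown fat markers, 0.25 for adenosine genes, -0.19 for branched-chain amino acid catabolism and 0.19 for housekeeping genes.

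**Figure D3:**
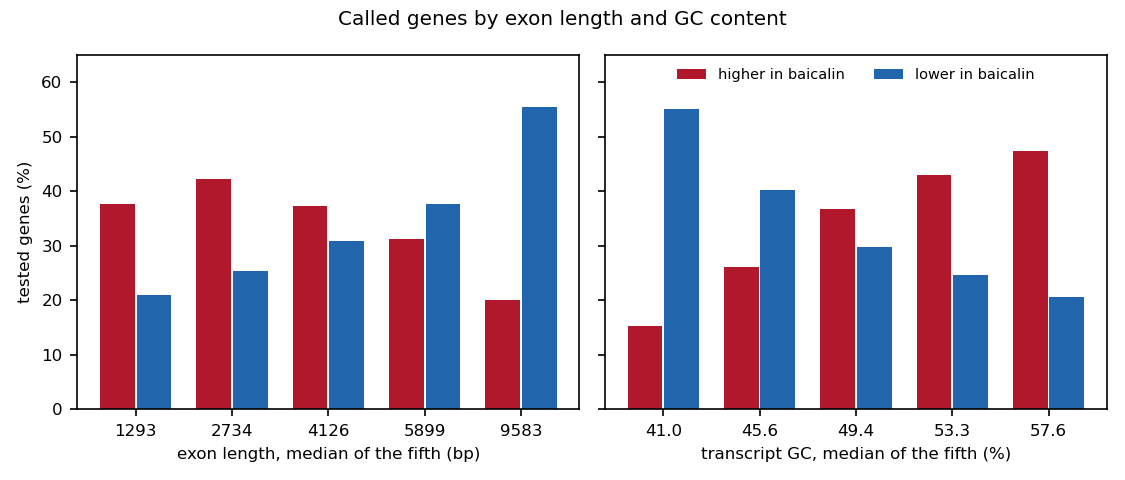
Percentage of tested genes called higher (red) or lower (blue) in baicalin, in 5 bins of equal size by exon length (left, axis in bp) and by transcript GC (right, axis in percent), each bin labelled by its median. The lower calls range from 21% among the shortest genes to 55.4% among the longest, and from 55.1% at the lowest GC to 20.5% at the highest.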

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

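The removal of length and GC trends was chosen after seeing the data, and the other settings were set before. Counts of higher genes ranged from 3472 (library size alone) to 4911 (no filter) and of lower genes from 3519 to 5811, within 1.5 times the counts given. Genes past 2-fold fell from 2053 to 734 with log2(FPKM + 1), 1185 with log2(FPKM + 0.1) and 744 with log2(FPKM + 1) without a filter. The added pseudocount shrinks the folds of low genes by construction. Leaving out each library gave 4424 to 4583 higher, 4397 to 4563 lower and 2116 to 2300 past 2-fold.

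With an estimated correlation 7 lists in place of 16 were called higher and 0 in place of 2 lower. With fry, which does not compare a list with other genes, 23 were higher and 5 lower. Leaving out each library gave 15 to 17 higher and 2 to 3 lower. Over all settings 398 list results kept their side of the threshold, 16 lost and 14 gained a call. Among the 9294 genes called in the main fit, those that a setting tested but did not call ranged from 36 (replicate block) to 1770 (log2(FPKM + 1) without a filter). They were 1329 with DESeq2, 1146 with library size alone and 601 to 730 on leaving out 1 library. For the genes given by the naming rule alone, 2637 results kept their call, 73 lost and 2 gained a call, and 3 changed direction. Most of these genes were picked for large changes or small p in these same data, which favours stable calls. Changes of direction were counted only for genes called in the main fit, the alternative or both. The 3 were Slc6a8 at -0.038 with library size alone and -0.027 with length and GC trends removed, and Kdm3a at 0.030 with these trends removed. The cause was not tested.

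Nothing in the sources used here says whether the replicate numbers pair the libraries. Deviations of same-numbered libraries correlate at 0.03, 0.04 and -0.002, and 4 of 6 libraries correlate best with their own number, a hint from the data and not the design. With the replicate block 4660 genes were higher, 4731 lower and 2064 past 2-fold, and 15 lists were higher and 2 lower, since the macrophage list was not called (adjusted p = 0.0528). Depth limits the statements on Adora1, Adora2a, Adora3, Lep, Slc2a4 and Ucp1, which have too few reads for a test.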

Other observations

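The tests on paralogs, on fibroblast markers and on Mdm2 and Slc35e3 were chosen only after the result was seen, as was the fit with length and GC trends removed.

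A pair of neighbouring genes was among the most abundant in DMSO and baicalin alike. Mdm2, the ubiquitin ligase that restrains p53 (chromosome 10, 117688875 to 117710758), ranked 6th of all genes by reads, with 7555 ± 162 CPM in DMSO and 6126 ± 185 CPM in baicalin (SD, n = 3 each, log2 fold change -0.30, adjusted p = 7.03e-10 with edgeR). Its neighbour Slc35e3 (117733679 to 117746365) ranked 17th, with 3744 ± 52.5 and 3451 ± 92.4 CPM. The genes on either side were far lower, with 10.3 ± 1.23 CPM of Cpm and 33.3 ± 0.47 CPM of Nup107 in DMSO. These 4 genes were looked at after their values were seen. The ferritin gene Fth1, which encodes an iron storage protein and is named after its value was seen, took 1.12% ± 0.05 of the counts in DMSO and 2.41% ± 0.04 in baicalin. The mean number of genes with reads differed by -1739 between baicalin and DMSO, although the mean total was higher in baicalin, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows.

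A hypothesis, prompted by the abundance of both genes, is that these cells may carry extra copies of a short segment of chromosome 10 that holds Mdm2 and Slc35e3. The less abundant of the pair stands 112-fold above the more abundant flanking gene, but the segment holds 2 genes, DNA was not measured, and a shared regulatory change cannot be told apart from a gain in copies. Reads from a copy elsewhere are argued against for Mdm2, of whose 50-mers 1.21% occur in annotated transcripts of another gene. For Slc35e3 this stays open, since 19.2% of its 50-mers do. The gene sharing the largest number of them is the pseudogene Gm7902, which had 5766 reads in all, against 55666 to 68535 reads of Slc35e3 in each library.

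The fall of interferon-stimulated genes (median log2 fold change -0.91, 26 of 30 lower) was weighed against bias and shared reads. With the length and GC trends removed the median was -0.72 (95% bootstrap interval over members -1.11 to -0.55). For these 30 genes this argues against the trends as the whole cause. The 19 members outside the Ifit, Oas, Mx and Gbp families had a median of -0.64 (interval -0.98 to -0.28), below 0. This argues against shared reads within families as the whole cause, although this interval does not lie wholly below the -0.5 first set as a bound. Both intervals treat list members as independent and do not measure the spread between samples. The estimated correlation between members was 0.143, and with it the list itself was not called (camera adjusted p = 0.075). Lower interferon signalling under baicalin remains a hypothesis, and no separate data on it were tested.

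The fall of mature adipocyte markers (median -0.70, 11 of 16 lower) is less settled, and the list was not called with an estimated correlation (adjusted p = 0.383). With the length and GC trends removed the list was still called lower (camera adjusted p = 0.00122), but its median was -0.63 with an interval from -1.47 to -0.0008, so that a part played by these trends cannot be told apart with 16 genes that go both ways. A lower share of fat cells as the whole cause would raise markers of preadipocytes and fibroblasts alike. Of the 20 called markers of that list 10 fell. This cannot decide the question, because called genes as a whole were split alike, with 4618 higher and 4676 lower. A lower share of fat cells alone therefore stays open. The DMSO cells themselves had few reads of several fat cell markers, with Adipoq at 1.66 CPM, although Lpl was at 1443 CPM and Fabp4 at 430 CPM. Cfd had 15 reads in DMSO and 0 in baicalin, whereas Retn had 4 and 28. Both were too low to test and are named after their values were seen. A change in the differentiation state, or in fibroblast genes beside a lower share, may also lie behind the fall and was not tested.

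The median of the ribosomal protein list was 0.41, and 0.26 (interval 0.18 to 0.34) with the length and GC trends removed. For the counts of called genes, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split, 1 of 10, gave 9294 called genes and 2053 past 2-fold. The highest of the others gave 0 and 0 with edgeR, with 44 to 68 genes at an unadjusted p under 0.05, and 0 with limma-voom. Each of these splits mixes DMSO and baicalin libraries in both groups. The treatment difference then widens the spread within groups, so these counts do not measure chance.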
